A study of Mus musculus with 17 samples.

How the data were processed

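The series holds 17 mouse samples. Each of 3 thymocyte groups (WT CD8, DKO CD8 and WT CD4) has 1 library for each of 4 histone marks and 1 input, and splenic CD8 cells have 2 Tcf1 libraries, from wild-type and Tcf1-deficient mice. The CD8 thymocytes were sorted as TCRβ-high, CD69-negative and CD24-negative, per the labels. Groups were taken from the sample titles. The WT CD4 samples also carry a phenotype label that names CD8 cells; their titles and source names say CD4, and the title was followed. Some samples were sequenced a second time for coverage, per the labels, which do not say which ones. The 13 processed files used here are 12 island lists, each for 1 histone library, and 1 Tcf1 peak list; the 3 inputs and the Tcf1-deficient library, described as the control of the Tcf1 peaks, were not analysed here on their own.

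The submitters' processing notes name FastQC, Bowtie2 2.2.5, SICER 1.1, MACS 1.4.2 and the mm9 build, with no role given for each tool. The deposited island lists give a read count per island, a whole number that was not normalized. Islands lie on a grid of 200 bp. The smallest gap between islands was 400 bp for H3K4me3, 600 bp for H3K27ac and H3K9ac and 800 bp for H3K27me3, so calling settings differed between marks and counts of islands are not compared across marks. The deposited Tcf1 list gives the authors' score per peak, of at least 50, which was used only to rank peaks within that list. Total reads per library are not given in the sources used here, so depth is described by reads within islands, a sum that moves with how much was called.

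For each mark, the islands of 2 libraries that shared at least 1 bp were merged into regions, and regions were counted by whether both libraries or 1 of them had an island. A region without an island in a library has an unknown number of reads there, so no fold is given for it. At regions of both libraries, the log2 ratio of island reads was centred on its median, and regions at least 2-fold above or below were counted. Reads of a library outside its own islands are not known and were not counted. Where 1 library has only a small island in a wide region, the ratio can be overstated, and its interval does not cover this. Counting noise was drawn once per comparison from Poisson counts around the pooled level with no difference. The draw had no calling threshold and no loss of reads outside islands, so it understates the spread of ratios without a difference. Intervals are exact Clopper-Pearson intervals at 95%, for shares and, conditional on the sum of both counts, for ratios. Lists of regions were placed among 10000 random lists of the same size matched on 10 strata of read density, but not on region width. Similarity is the Jaccard index in bp, and lists were trimmed to equal covered length by keeping the islands with the most reads per bp. Tcf1 peaks were shuffled 100 times within each chromosome, between its outermost islands. Overlaps of changes in pairs of marks were set beside the product of the list sizes over the number of regions. That number was first taken as all regions of either mark and then, after those values had been seen, as regions where both marks were called, since only these can change in both; both versions are reported.

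An mm9 gene annotation was not used here: the gene table at hand is of another build, and coordinates were not converted. The planned counts of genes with promoter islands, 17 gene lists, the place of Tcf1 peaks relative to genes and the planned named genes, with the deleted Tcf7 and Lef1 first, were therefore not run, and the deletion was not checked in these data. Named regions followed the rule fixed for this case before the data were examined: per mark and comparison, the 3 regions with the most reads in each direction among those of 1 library, and the 3 with the largest ratio in each direction among shared regions with at least 100 reads in the higher library. Of these the text gives the first for each direction, with more for H3K27ac and H3K9ac of the first comparison. No places were filtered out for high signal in many libraries. Region classes by H3K4me3 and by Tcf1 peak were set after the files were seen.

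Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Overlap, merging and shared length were checked against bedtools 2.31.1, which gave equal values. The ratio step was tested on simulated data for the H3K27ac comparison of DKO CD8 and WT CD8 over 11068 shared regions, with 200 changed 3-fold: 96% of those raised and 96% of those lowered were found beyond 2-fold, as were 1.21% of unchanged regions. With 200 changed 6-fold, 100% of each were found. The simulated counts had no calling threshold and no loss of reads outside islands. Of 100 random lists of these regions, 6 fell outside the central 95% of matched lists. Alternatives covered equal covered length, islands with more reads than their list's median, an overlap of at least 50% of an island, total island reads as scale, at least 50 reads in the higher library (before scaling and, chosen after seeing the data, with both libraries brought to the middle of their median ratio), Tcf1 peaks above the median score and the midpoint of each peak.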

Results

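The series mapped 4 histone modifications by chromatin immunoprecipitation and sequencing (ChIP-seq) in mature mouse thymocytes, and the binding of the transcription factor Tcf1 in splenic CD8 T cells. Of these modifications, H3K4me3 is typical of active promoters, H3K27ac and H3K9ac of active promoters and enhancers, and H3K27me3 of regions silenced by Polycomb proteins. The thymocytes formed 3 groups: wild-type CD8 cells (WT CD8), CD8 cells from mice in which CD4-Cre had deleted Tcf1 and Lef1 (DKO CD8), and wild-type CD4 cells (WT CD4). Tcf1 and Lef1 are related DNA-binding factors that act in T cell development. Each group had 1 library per modification, so no difference between groups has a replicate check, no p-value is given, and intervals cover counting error only. Regions are named by chromosome, start and end in the mm9 build; genes at these regions were not analysed here.

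Islands, the enriched intervals called in each library, held between 248234 reads (WT CD8 H3K9ac) and 4025243 reads (WT CD4 H3K27me3). For H3K27ac, WT CD8 had 56985 islands over 83.5 Mb with 24.6 reads per kb, DKO CD8 had 29636 over 59.1 Mb with 33.1 reads per kb, and WT CD4 had 24476 over 64.2 Mb with 39.1 reads per kb. For H3K27me3, WT CD8 had 34756 islands over 121 Mb with 21.2 reads per kb, DKO CD8 had 23933 over 96.1 Mb with 32.0 reads per kb, and WT CD4 had 34013 over 142 Mb with 28.4 reads per kb. H3K4me3 islands numbered 42013 in WT CD8, 23411 in DKO CD8 and 28449 in WT CD4, with a median width of 800 bp in each group. H3K9ac islands numbered 9860 in WT CD8, 6516 in DKO CD8 and 32651 in WT CD4. In 9 of the 12 histone libraries the island with the most reads lay on chromosome 11 between 3017601 and 3100800, with 5878 to 26890 reads.

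The first comparison, DKO CD8 against WT CD8, addresses how the loss of Tcf1 and Lef1 bears on histone marks in CD8 cells. Most H3K27ac regions were called in 1 library only: of 74492 merged regions, 11068 (14.9%, 95% interval 14.6 to 15.1) had an island in both, 18397 in DKO CD8 alone and 45027 in WT CD8 alone. The same order held for H3K4me3 (7608 shared, 15700 in DKO CD8 alone and 34210 in WT CD8 alone), for H3K27me3 (9092, 14150 and 23304) and for H3K9ac (2810, 3702 and 6988). Regions of a single library were weak: the median was 22 reads for H3K27ac in WT CD8 alone and 25 in DKO CD8 alone, while shared H3K27ac regions had medians of 31 reads in WT CD8 and 88 in DKO CD8. With each pair of lists trimmed to equal covered length, WT CD8 alone had more regions than DKO CD8 alone for each mark. H3K4me3 moved most (20816 in WT CD8 alone and 16802 in DKO CD8 alone). Trimmed lists leave nearly the same length outside each other. These counts therefore show how islands divide that sequence, not which library had more of it. With WT CD4 as the wild-type reference instead, chosen after seeing the data, the order turned for H3K27ac, with 12108 regions in DKO CD8 alone and 7797 in WT CD4 alone.

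**Figure D1:**
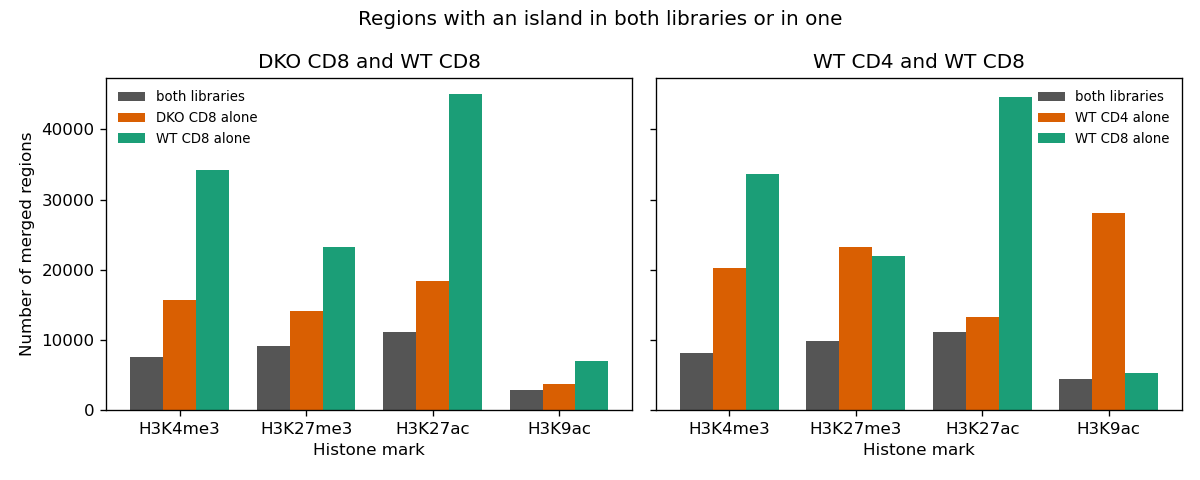
Merged regions (number, vertical axis) by histone mark with an island in both libraries (grey), in DKO CD8 or WT CD4 alone (orange) or in WT CD8 alone (green), 1 library per group. WT CD8 alone is the tallest bar for H3K27ac in both panels (45027 and 44566 regions), and WT CD4 alone is the tallest for H3K9ac (28148 regions).

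For H3K27ac, regions of WT CD8 alone differed from the others in place. Per Mb of chromosome, H3K27ac regions of WT CD8 alone varied by 5.77% (coefficient of variation over the autosomes), against 25.7% for shared regions and 19.9% for DKO CD8 alone. Chromosome X held 7.48% of the H3K27ac regions of WT CD8 alone, 1.97% of the shared ones and 2.01% of those of DKO CD8 alone, and made up 6.34% of the sequence between the outermost islands. H3K27me3 regions of WT CD8 alone were also evenly spread (8.85%, against 26.5% for shared regions), whereas H3K9ac regions of WT CD8 alone were not (29.8%). For H3K4me3 the regions of either library alone were more evenly spread (8.60% in WT CD8 alone and 13.1% in DKO CD8 alone) than shared ones (23.7%), and chromosome X held more of DKO CD8 alone (6.59%) than of WT CD8 alone (4.71%) or of shared regions (3.29%).

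Of the regions in 1 library only, those with the most reads mostly had islands in several libraries. For H3K27ac in DKO CD8 alone they were chromosome 11, 3021001 to 3100200 (13581 reads), chromosome 5, 108150001 to 108151000 (756 reads), and chromosome 1, 90148801 to 90167000 (687 reads), each also a WT CD4 H3K27ac region. For H3K27ac in WT CD8 alone they were chromosome 2, 98506201 to 98507600 (7411 reads), chromosome 10, 7229201 to 7235400 (3222 reads), and chromosome 7, 67002201 to 67050400 (3054 reads), each also overlapping a WT CD8 H3K27me3 island. The strongest H3K27me3 region of WT CD8 alone, chromosome 9, 2999801 to 3039400, held 111889 reads and was called in no other of the 12 histone libraries. The strongest H3K27me3 region of DKO CD8 alone, chromosome 1, 90118801 to 90155200, held 1863 reads and overlapped islands of 11 of the 12 histone libraries. For H3K4me3 the strongest regions were chromosome 2, 98506201 to 98507600, in DKO CD8 alone (8885 reads) and chromosome 6, 47600801 to 47637200, in WT CD8 alone (2235 reads). For H3K9ac in DKO CD8 alone they were chromosome X, 92130401 to 92163400 (928 reads), and chromosome 6, 124829601 to 124839000 (667 reads), the latter with an H3K9ac island in WT CD4 too. The strongest H3K9ac region of WT CD8 alone was chromosome 17, 39979801 to 39985800 (2767 reads). No filter for places with high signal in many libraries was applied, so these regions are not read as differences between groups. Chromosome 2, 98506201 to 98507600, had islands of H3K27ac and H3K27me3 in WT CD8 and of H3K4me3 in DKO CD8.

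At regions called in both libraries, reads were compared after dividing by the median ratio, which was 2.72-fold in favour of DKO CD8 for H3K27ac, 2.24-fold for H3K27me3, 1.71-fold for H3K9ac and 1.06-fold for H3K4me3. Relative to that median, 894 H3K27ac regions were at least 2-fold higher in DKO CD8 and 1681 at least 2-fold lower, where counting noise alone gave 116 and 35. For H3K27me3 the counts were 698 higher and 1885 lower (noise 11 and 4), for H3K4me3 436 and 563 (noise 80 and 71), and for H3K9ac 111 and 100 (noise 31 and 10). The noise draw leaves out the calling of islands, so an excess over it can arise without a difference between groups. The split depended on the scale: divided by total island reads, 7991 H3K27ac regions were higher and 197 lower, 4190 H3K27me3 regions higher and 568 lower, 2409 H3K4me3 regions higher and 100 lower, and 663 H3K9ac regions higher and 14 lower. On the median scale with at least 50 reads in the higher library after scaling, a minimum chosen after seeing the data, the order held for each mark, with 818 H3K27ac regions higher and 979 lower, 118 and 260 for H3K4me3, 59 and 44 for H3K9ac, and 698 and 1724 for H3K27me3.

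Among shared regions with at least 100 reads in the higher library, the H3K27ac regions highest in DKO CD8 were chromosome 7, 87558401 to 87570200 (log2 ratio 3.43, 95% interval 2.57 to 4.45), chromosome 11, 115086601 to 115094800 (2.92, 2.18 to 3.78, with a Tcf1 peak), and chromosome 10, 80635601 to 80642600 (2.81, 2.01 to 3.74). The lowest were chromosome 1, 58379001 to 58387400 (-5.34, -6.20 to -4.59), chromosome 17, 67884401 to 67891400 (-4.99, -5.85 to -4.22), and chromosome 16, 56039801 to 56049400 (-4.84, -5.61 to -4.16), and each of them also had a WT CD8 H3K27me3 island. For H3K27me3 the highest was chromosome X, 11650401 to 11669200 (3.03, 2.58 to 3.52, with a Tcf1 peak) and the lowest chromosome 5, 144534201 to 144559800 (-4.83, -5.30 to -4.39). For H3K4me3 the highest was chromosome 17, 44871401 to 44873600 (3.01, 2.14 to 4.01) and the lowest chromosome 17, 35575601 to 35578400 (-2.98, -3.86 to -2.20). For H3K9ac the highest was chromosome 6, 48685801 to 48692800 (1.96, 1.30 to 2.70) and the lowest chromosome 16, 35981601 to 35984800 (-2.20, -2.77 to -1.66, with a Tcf1 peak). Such extremes can rest on a small island in a wide region. The H3K27ac region on chromosome 7 had 11 WT CD8 reads over 11.8 kb, and that on chromosome 1 had 15 DKO CD8 reads over 8.4 kb. Reads outside islands are not known there, so the intervals do not bound these ratios.

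Shared H3K27ac regions differed by class. The 4766 that overlapped an H3K4me3 region of all 3 groups had a median log2 ratio of 0.27 in DKO CD8 over WT CD8, above each of 10000 random lists of equal strength (median of these lists 0.09). The 3685 without any H3K4me3 island had a median of -0.38, below each random list (-0.14). The random lists were matched on read density and not on width. WT CD4 over WT CD8 gave the same signs (0.14 and -0.20) with the same WT CD8 library as denominator. On total island reads each DKO CD8 median for H3K27ac lies 1.51 higher and each WT CD4 median 1.60 higher, so that both classes are above 0. For H3K9ac the same classes had medians of 0.02 and -0.01 in DKO CD8 and 0.18 and -0.80 in WT CD4 (random lists 0.00, 0.06, 0.07 and -0.37); on total island reads these shift by 0.59 in DKO CD8 and -0.89 in WT CD4, which turns the sign of -0.01 and of 0.18.

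The second comparison, WT CD4 against WT CD8, gives the difference between the lineages for the same marks. H3K27ac again had far more regions in WT CD8 alone (44566) than in WT CD4 alone (13235), with 11153 shared. H3K9ac had the opposite order, with 28148 regions in WT CD4 alone, 5324 in WT CD8 alone and 4457 shared. H3K27me3 was close to even, with 23240 regions in WT CD4 alone and 21984 in WT CD8 alone, and H3K4me3 had 20295 and 33694. At equal covered length the H3K9ac regions of WT CD4 alone numbered 8304, against 6339 in WT CD8 alone. The order for H3K27me3 turned, with 17725 in WT CD4 alone and 22500 in WT CD8 alone. As in the first comparison, counts at equal length reflect how islands divide the sequence, so neither order shows which library had more.

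The regions of 1 library with the most reads in this comparison often overlapped those of the first. In WT CD4 alone they were chromosome 11, 3018001 to 3100800, for H3K27ac (14893 reads), chromosome 1, 90119801 to 90167000, for H3K27me3 (2539 reads), and chromosome 10, 7229201 to 7235400, for H3K4me3 (3392 reads) and H3K9ac (4279 reads). In WT CD8 alone they were chromosome 2, 98506201 to 98507600, for H3K27ac (7411 reads), chromosome 9, 2999801 to 3039400, for H3K27me3 (111889 reads), chromosome 7, 67006401 to 67047600, for H3K4me3 (2809 reads), and chromosome 8, 57975001 to 57982800, for H3K9ac (239 reads). Without a filter for high signal in many libraries, these regions too are not read as differences between groups.

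At shared regions the median ratio favoured WT CD4 3.68-fold for H3K27ac, 2.61-fold for H3K27me3, 2.31-fold for H3K9ac and 1.61-fold for H3K4me3. Relative to it, 703 H3K27ac regions were at least 2-fold higher and 1507 lower in WT CD4, with 650 and 1826 for H3K27me3, 492 and 647 for H3K4me3, and 275 and 510 for H3K9ac. Divided by total island reads, the higher and lower counts became 8660 and 199 for H3K27ac, 3390 and 732 for H3K27me3, 3246 and 105 for H3K4me3, and 14 and 1923 for H3K9ac. With at least 50 reads in the higher library after scaling, the order on the median scale held for H3K27ac (686 higher and 994 lower) and H3K27me3 (650 and 1693), and turned for H3K4me3 (271 and 226) and H3K9ac (222 and 112). The shared H3K27ac region highest in WT CD4 was chromosome 11, 99056401 to 99067200 (log2 ratio 3.47, 2.61 to 4.48), and the lowest was chromosome 10, 124014201 to 124021000 (-5.09, -5.86 to -4.41). For H3K27me3 these were chromosome 4, 118214401 to 118223000 (4.17, 3.68 to 4.70), and chromosome 5, 95140401 to 95163600 (-4.89, -5.38 to -4.42). For H3K4me3 they were chromosome X, 166609201 to 166635000 (5.12, 4.44 to 5.91), and chromosome 1, 87466001 to 87472000 (-3.91, -4.79 to -3.14). For H3K9ac they were chromosome 19, 24986001 to 24993600 (2.49, 1.76 to 3.33), and chromosome 4, 154214801 to 154227200 (-5.01, -5.73 to -4.37). The H3K4me3 region on chromosome X had 17 WT CD8 reads in islands over 25.8 kb. Its reads outside islands are not known, so the interval does not bound the ratio.

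The 3 groups were then compared with one another by the sequence their islands cover. DKO CD8 overlapped WT CD4 more than WT CD8 for H3K27ac (Jaccard index 38.5% against 12.9%), H3K27me3 (39.7% against 22.9%) and H3K4me3 (16.0% against 12.5%). WT CD8 overlapped WT CD4 about as little as it overlapped DKO CD8, at 13.6% for H3K27ac, 21.1% for H3K27me3 and 11.8% for H3K4me3. For H3K9ac, DKO CD8 overlapped WT CD8 more (15.9%) than WT CD4 (12.3%), and this order turned at equal covered length (17.3% and 26.8%). Of the H3K27ac regions of DKO CD8 alone against WT CD8, 39.9% had a WT CD4 island, whereas 3.64% of those of WT CD8 alone did. Read density was compared across regions of all 3 groups with at least 50 reads in the highest library. Over 9221 such H3K27ac regions it correlated most between DKO CD8 and WT CD4 (Spearman's rho 0.82, against 0.66 for DKO CD8 and WT CD8 and 0.70 for the wild-type pair). Over 2091 H3K9ac regions it did so too (0.68, 0.54 and 0.59), unlike the Jaccard index as deposited. These rho values are across regions, which are not independent replicates. Each density was divided by the length of the same merged region, so part of each rho can come from this shared length.

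**Figure D2:**
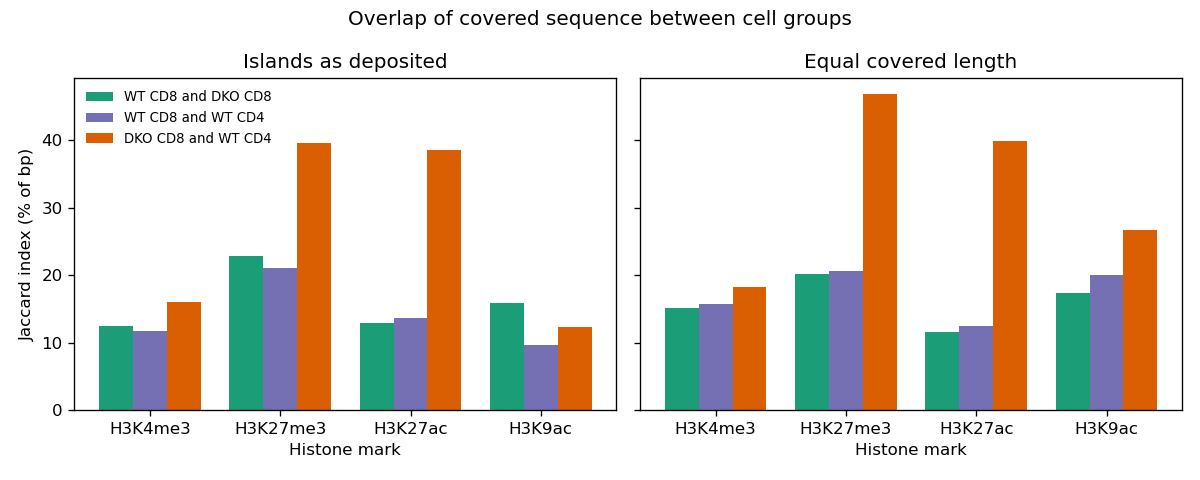
Jaccard index (% of bp, vertical axis) for each pair of cell groups and each histone mark, with the islands as deposited (left) and at equal covered length (right), 1 library per group. DKO CD8 and WT CD4 form the highest bar for H3K27ac in both panels (38.5% and 39.9%), while for H3K9ac they do so only at equal covered length.

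Regions called in all 3 groups for H3K27ac numbered 9885. A further 6379 were called in DKO CD8 and WT CD4 without WT CD8, 1255 in the wild-type groups without DKO CD8, and 1009 in the CD8 groups without WT CD4. Regions of a single group numbered 43387 in WT CD8, 11061 in DKO CD8 and 6510 in WT CD4.

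Tcf1 binding was mapped in splenic CD8 cells, as 7807 peaks with a median width of 407 bp. H3K27ac islands held most of them: 55.8% of peaks (54.7 to 56.9) lay in those of WT CD8, 74.8% (73.8 to 75.7) in those of DKO CD8 and 81.5% (80.6 to 82.3) in those of WT CD4, against 4.26%, 3.09% and 3.22% after shuffling within chromosomes. H3K9ac islands held 23.0% in WT CD8, 28.5% in DKO CD8 and 49.6% in WT CD4, and H3K4me3 islands 34.5%, 35.5% and 41.6%. H3K27me3 islands held few, at 3.34% in WT CD8 and 5.73% in WT CD4, which were below the shuffled 5.45% and 6.77%, and at 7.71% in DKO CD8, which was above the shuffled 4.57%. By class of chromatin, 31.4% of peaks lay in H3K4me3 regions of all 3 groups and 39.3% in H3K27ac islands of any group without H3K4me3, and the highest score, 477.81, was of the latter class at chromosome 5, 29532304 to 29532665.

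Tcf1 peaks were then set beside the regions that differed between DKO CD8 and WT CD8. For H3K27ac, 35.8% of shared regions (34.9 to 36.7) held a peak, 6.66% (6.30 to 7.03) of those of DKO CD8 alone and 0.369% (0.315 to 0.429) of those of WT CD8 alone. The order was the same for H3K9ac (47.7%, 18.8% and 5.55%), H3K4me3 (30.0%, 2.66% and 1.17%) and H3K27me3 (3.34%, 2.0% and 0.279%). For H3K27ac it held at each width, with 19.5%, 5.13% and 0.310% at up to 1 kb and 45.6%, 13.5% and 0.444% over 3 kb; for H3K27me3 between 1 and 3 kb, shared regions (0.975%) lay below those of DKO CD8 alone (1.44%), with overlapping intervals, and for H3K4me3 over 3 kb, 0 of 50 regions of DKO CD8 alone held a peak, which allows up to 7.11%. With WT CD4 as the wild-type reference instead, chosen after seeing the data, 1.41% of H3K27ac regions of DKO CD8 alone and 6.43% of those of WT CD4 alone held a peak. The order of these classes also turned for H3K9ac (3.20% in DKO CD8 alone and 5.64% in WT CD4 alone) and H3K4me3 (1.01% and 2.66%), but not for H3K27me3 (2.05% and 0.409%). No shuffled share was computed for any class of regions, so these shares have no chance level beside them. Background islands in the WT CD8 list would lower its share, so the gap between classes is not read as an effect of Tcf1.

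**Figure D3:**
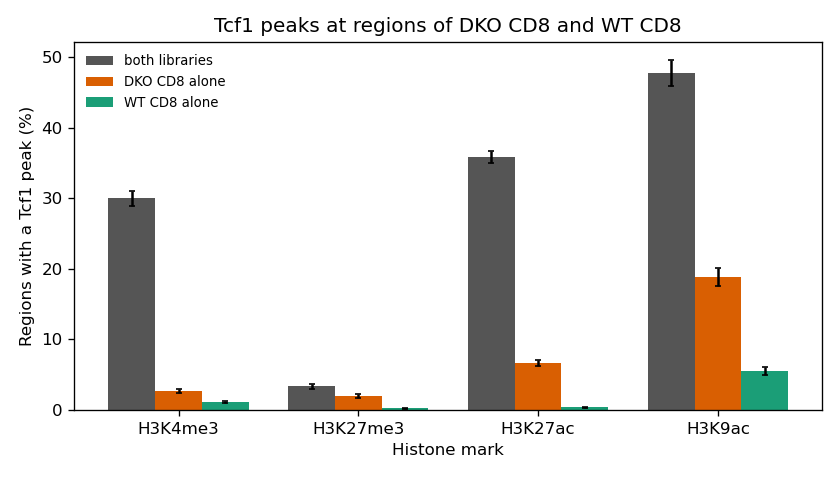
Share of regions with a Tcf1 peak (%, vertical axis) by histone mark, for regions in both libraries (grey), in DKO CD8 alone (orange) and in WT CD8 alone (green), with 95% Clopper-Pearson intervals that cover counting error only. Shared regions have the highest share for each mark, up to 47.7% for H3K9ac.

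Where both libraries had a region, those with a Tcf1 peak had relatively more H3K27me3 in DKO CD8: the median log2 ratio was 0.37 over 304 regions, above each random list (0.04). For H3K27ac it was 0.18 over 3967 regions (random lists 0.05), for H3K4me3 0.07 over 2280 (0.01) and for H3K9ac 0.05 over 1341 (0.00). The random lists were not matched on width. Of the 304 H3K27me3 regions 288 were over 3 kb, against 7626 of all 9092 shared ones. For H3K27ac it was 1531 of 3967 against 3356 of 11068, and for H3K9ac 198 of 1341 against 339 of 2810. For H3K4me3 the share was lower (66 of 2280 against 322 of 7608). Whether width accounts for these medians was not tested. H3K27me3 was also relatively higher in DKO CD8 at the 237 shared regions that overlapped an H3K4me3 region of all 3 groups (0.24, random lists 0.05), where the WT CD4 median over WT CD8 was -0.02 at 228 regions (0.02). Against WT CD8, the WT CD4 medians at Tcf1 peaks were 0.21 for H3K27me3, 0.13 for H3K27ac, 0.22 for H3K9ac and 0.09 for H3K4me3 (random lists 0.02, 0.01, 0.05 and 0.03), with the same WT CD8 library as denominator. On total island reads each of these DKO CD8 medians lies higher, by 0.91 for H3K27me3, 1.51 for H3K27ac, 0.72 for H3K4me3 and 0.59 for H3K9ac. The WT CD4 medians shift by 0.73, 1.60, 0.85 and -0.89, which puts the H3K9ac median below 0 and the H3K27me3 median at H3K4me3 regions above 0.

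Marks were finally combined within each group. Of 6019 H3K4me3 regions called in all 3 groups, 12.4% (11.6 to 13.3) also had an H3K27me3 island in DKO CD8, 7.61% (6.95 to 8.31) in WT CD4 and 4.19% (3.69 to 4.72) in WT CD8. At the same 6019 regions an H3K27ac island was found in 97.1% for DKO CD8, 97.2% for WT CD4 and 80.5% for WT CD8, and an H3K9ac island in 60.0%, 93.7% and 52.6%. Over all H3K4me3 islands of each group, in place of these shared regions, the order of the groups for H3K27me3 was the opposite. An H3K27me3 island overlapped 11.5% (11.1 to 11.9) of 23411 islands in DKO CD8, 19.4% (18.9 to 19.8) of 28449 in WT CD4 and 24.8% (24.4 to 25.3) of 42013 in WT CD8. These are unlike sets of islands. Regions of WT CD8 alone were evenly spread for both marks (8.60% for H3K4me3 and 8.85% for H3K27me3), so background islands in both lists could raise the WT CD8 share, which was not tested. Among regions where both H3K27ac and H3K9ac were called in DKO CD8 or WT CD8, 472 were of DKO CD8 alone for each mark, where independent lists would give 381, and 1143 were of WT CD8 alone for each mark, against 573. This excess depended on the background, which was chosen after seeing the data: over all regions of either mark, the 472 compare with 849 and the 1143 with 3928, below chance.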

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

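No paired analysis was possible because each group has 1 library per mark. Settings that need a gene annotation (promoter windows, gene bodies and gene lists) were not run. The WT CD4 reference, the minimum of 50 reads after scaling, the equal-length H3K27me3 lists, the shares over all H3K4me3 islands and, for pairs of marks, the background of regions where both were called were chosen after seeing the data, the last after the values over all regions of either mark. Islands with under 50% of their length covered by the other list were also counted, beside the merged regions of 1 library. No such count differed from that of regions by over 1.5 times, though islands and merged regions are unlike units. Where values moved, the cause was not tested, except that the settings by median and by 50 reads keep fewer regions or peaks by construction. What depth limits was not tested, since total reads per library are not given in the sources used here; H3K27ac regions in 1 library had medians of 22 reads in WT CD8 alone and 25 in DKO CD8 alone.

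At equal covered length, regions of WT CD8 alone against DKO CD8 were 20816 for H3K4me3, and of WT CD4 alone 8304 for H3K9ac. With islands above the median reads, regions of DKO CD8 alone were 5867 for H3K4me3, 6464 for H3K27me3, 8020 for H3K27ac and 1630 for H3K9ac; of WT CD8 alone against it 13437 for H3K4me3, 10985 for H3K27me3, 21135 for H3K27ac and 2730 for H3K9ac. In the lineage comparison, WT CD4 alone had 6920 for H3K4me3, 11069 for H3K27me3, 5805 for H3K27ac and 13238 for H3K9ac, and WT CD8 alone 13056 for H3K4me3, 10642 for H3K27me3, 21167 for H3K27ac and 1789 for H3K9ac. With WT CD4 as reference, DKO CD8 alone had 8738 for H3K27me3, 12108 for H3K27ac and 1909 for H3K9ac, and the wild type alone 20831 for H3K4me3, 7797 for H3K27ac and 27984 for H3K9ac, so WT CD4 alone had fewer H3K27ac regions than DKO CD8 alone. At equal covered length H3K27me3 had 17725 regions in WT CD4 alone and 22500 in WT CD8 alone, the reverse of their order as deposited. Counts at equal covered length reflect how islands divide the sequence, since the trimmed lists leave nearly the same length outside each other.

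On total island reads, regions higher in DKO CD8 were 2409 for H3K4me3, 4190 for H3K27me3, 7991 for H3K27ac and 663 for H3K9ac, and lower 100 for H3K4me3, 568 for H3K27me3, 197 for H3K27ac and 14 for H3K9ac. Those higher in WT CD4 were 3246 for H3K4me3, 3390 for H3K27me3, 8660 for H3K27ac and 14 for H3K9ac, and lower 105 for H3K4me3, 732 for H3K27me3, 199 for H3K27ac and 1923 for H3K9ac. With at least 50 reads, counted before scaling, DKO CD8 had 134 for H3K4me3 higher and 249 for H3K4me3, 579 for H3K27ac and 22 for H3K9ac lower, and WT CD4 141 for H3K4me3, 1152 for H3K27me3, 659 for H3K27ac and 44 for H3K9ac lower. Higher counts beside these were 894 for H3K27ac and 101 for H3K9ac in DKO CD8, and 390 for H3K4me3, 650 for H3K27me3, 703 for H3K27ac and 275 for H3K9ac in WT CD4. An H3K27ac or H3K27me3 region called higher must already exceed this minimum, given the smallest WT CD8 islands (10 and 15 reads) and the median ratios, so it removes only lower regions there, and mostly lower ones for H3K9ac and, in WT CD4, H3K4me3. The order of its counts therefore says nothing about weak regions. With 50 reads in the higher library after scaling, DKO CD8 had 118 for H3K4me3 and 59 for H3K9ac higher and 260 for H3K4me3, 979 for H3K27ac and 44 for H3K9ac lower, and WT CD4 271 for H3K4me3 higher and 226 for H3K4me3, 994 for H3K27ac and 112 for H3K9ac lower. Higher regions outnumbered lower ones there, where they had not before, for H3K4me3 and H3K9ac in WT CD4 but for no other mark or comparison. The smallest islands of each library still bound the 2 directions differently.

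Tcf1 shares (%) with peaks above the median score were 15.4 for H3K4me3, 1.52 for H3K27me3, 20.8 for H3K27ac and 26.5 for H3K9ac in shared regions, 1.35 for H3K4me3, 1.02 for H3K27me3, 3.19 for H3K27ac and 10.3 for H3K9ac in DKO CD8 alone and 0.520 for H3K4me3, 0.107 for H3K27me3, 0.222 for H3K27ac and 2.86 for H3K9ac in WT CD8 alone. At equal covered length they were 32.1 for H3K4me3 and 39.0 for H3K27ac in shared regions, 3.49 for H3K4me3 and 8.85 for H3K27ac in DKO CD8 alone and 1.47 for H3K4me3, 0.304 for H3K27ac and 6.21 for H3K9ac in WT CD8 alone. With WT CD4 as reference they were 33.9 for H3K4me3, 31.1 for H3K27ac and 43.9 for H3K9ac in shared regions, 1.01 for H3K4me3, 1.41 for H3K27ac and 3.20 for H3K9ac in DKO CD8 alone and 2.66 for H3K4me3, 0.409 for H3K27me3 and 6.43 for H3K27ac in WT CD4 alone, where the order of the last 2 turned for each mark except H3K27me3.

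The Jaccard index of DKO CD8 with WT CD4 minus that with WT CD8, in percentage points, became 3.15 for H3K4me3, 26.6 for H3K27me3, 28.3 for H3K27ac and 9.47 for H3K9ac at equal covered length; for H3K9ac it had been -3.65, so its sign turned. H3K4me3 regions with H3K27me3 became 3.47% for WT CD8 and 6.65% for WT CD4, and DKO CD8 stayed at 12.4%. Over all H3K4me3 islands of each group, in place of the 6019 regions of all 3 groups, the shares were 24.8% for WT CD8, 11.5% for DKO CD8 and 19.4% for WT CD4. The order of the groups turned, over sets of islands that differ between groups.

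Overlaps of changes in pairs of marks, as observed over independent lists, were above 1 where both marks were called and below 1 over all regions of either mark. The latter were 0.556 for H3K27ac with H3K9ac, 0.337 for H3K27ac with H3K4me3 and 0.501 for H3K4me3 with H3K9ac in DKO CD8 alone, and 0.291 for H3K27ac with H3K9ac, 0.576 for H3K27ac with H3K4me3 and 0.280 for H3K4me3 with H3K9ac in WT CD8 alone. In the lineage comparison they were 0.706 for H3K27ac with H3K9ac, 0.634 for H3K27ac with H3K4me3 and 0.454 for H3K4me3 with H3K9ac in WT CD4 alone, and 0.391 for H3K27ac with H3K9ac, 0.620 for H3K27ac with H3K4me3 and 0.398 for H3K4me3 with H3K9ac in WT CD8 alone. Regions of 1 mark only enter the larger background and cannot change in both. Of the ratios of shared regions selected by the naming rule, 36 moved beyond their intervals on total island reads and 12 did not, and none changed sign. By peak midpoint the shares of Tcf1 peaks in islands could not rise, by construction, and were lower in all 12 histone libraries. With peaks above the median score, 9 of the 12 shares moved beyond their intervals.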

Other observations

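The tests of H3K27ac similarity and of island width below were chosen after their results were seen, and the other tests before. Opposite marks in different groups were rare. WT CD8 had most of those counted from H3K27ac islands, and WT CD4 had the most counted from H3K27me3 islands. H3K27ac islands of WT CD8 that lay on H3K27me3 islands of both other groups, with no H3K27ac there and no H3K27me3 in WT CD8, numbered 630, none of them with a Tcf1 peak. The corresponding H3K27ac islands numbered 87 for DKO CD8 and 12 for WT CD4. The strongest for DKO CD8 was chromosome 17, 29438201 to 29443800, with 106 H3K27ac reads there and H3K27me3 islands of 66 reads in WT CD8 and 114 in WT CD4. In the reverse direction, H3K27me3 islands on H3K27ac of both other groups numbered 28 for DKO CD8, 45 for WT CD8 and 62 for WT CD4. The strongest for DKO CD8 was chromosome 1, 178922601 to 178928800, with 146 reads. These regions were chosen by reads after the data were seen. No chance level was computed for the counts of opposite marks. The 630 came from the longest H3K27ac list (56985 islands), and background islands in it would raise that count.

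Chromosome X also differed between groups. It held 5.54% of H3K4me3 islands in DKO CD8, 4.44% in WT CD8 and 1.84% in WT CD4. For H3K27ac the shares were 1.99% in DKO CD8, 6.30% in WT CD8 and 1.89% in WT CD4. Chromosome X made up 6.34% of the sequence between the outermost islands. The highest shares lie near that of evenly spread islands, so they are not read as differences between the cells. Tcf1 peaks in H3K27ac islands of the wild-type groups but not of DKO CD8 numbered 136, or 1.74% (1.46 to 2.06). The peaks with H3K27ac in DKO CD8 and WT CD4 but not WT CD8 numbered 1502, or 19.2% (18.4 to 20.1), and those with it in both CD8 groups but not WT CD4 numbered 30. The median scores of these classes were 90.4, 73.3 and 99.8, against 80.9 for the 4125 peaks with H3K27ac in all 3 groups. The highest score of the first class, 452.7, lay at chromosome 2, 17593163 to 17593707.

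The first pattern weighed is that WT CD8 alone had more H3K27ac regions than DKO CD8 alone. If background islands of the WT CD8 library were the cause, these regions were predicted to overlap WT CD8 islands of H3K27me3, the opposite mark, more often than shuffled regions. Of regions of DKO CD8 alone, 14.3% overlapped a DKO CD8 H3K27me3 island and 9.21% a WT CD8 one. Of regions of WT CD8 alone, 40.2% overlapped a WT CD8 H3K27me3 island, against 6.5% for shuffled regions and 8.45% for shared regions. If acetylation were present in WT CD8 and lost in DKO CD8, the regions were predicted to carry WT CD8 H3K9ac at least 0.5 times as often as regions of DKO CD8 alone carry DKO CD8 H3K9ac, and the ratio of these shares was 0.789 (2.63% against 3.33%, where shuffled regions gave 1.05% and 0.914% and shared regions 33.8%). Both predictions were met. The second bar was low, since regions of DKO CD8 alone rarely carried H3K9ac either, so meeting it does not weigh against background. Regions of WT CD8 alone were also evenly spread (coefficient of variation 5.77%, against 25.7% for shared regions). Chromosome X held 7.48% of them and made up 6.34% of the sequence. These values go with background, while a loss of acetylation at some of the regions stays open. How many regions each accounts for was not determined. A difference between the mice or preparations was not tested.

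The second pattern is that DKO CD8 H3K27ac islands overlapped WT CD4 islands more than WT CD8 islands. Low enrichment of the WT CD8 library is a candidate explanation: at H3K4me3 regions of all 3 groups, a WT CD8 H3K27ac island was found in 80.5% (79.4 to 81.5), against 97.2% (96.8 to 97.6) for WT CD4. CD4-like acetylation in DKO CD8 was tested on regions that WT CD8 shared with 1 other group. Those shared with WT CD4 outnumbered those shared with DKO CD8 1.24 to 1, between the bounds set for and against it. This ratio cannot decide the question, since DKO CD8 islands fully like those of WT CD4 would leave few regions in either class. With 1 WT CD8 library the genotype and that library's enrichment cannot be told apart for this explanation.

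The third pattern, a larger share of H3K4me3 regions with an H3K27me3 island in DKO CD8, holds at the 6019 regions of all 3 groups. It turns over all H3K4me3 islands of each group (11.5% in DKO CD8, 19.4% in WT CD4 and 24.8% in WT CD8). Those islands differ between groups, and background islands of both marks could raise the WT CD8 share, so the turn does not weigh against the pattern at the 6019 regions. Of these regions, 400 had an H3K27me3 island in DKO CD8 and in neither wild-type group, with a median island width of 1800 bp (bootstrap interval 1600 to 2000). The comparison written before this was seen, with 2600 bp for all DKO CD8 H3K27me3 islands, is void. The 6954 islands away from these regions that overlap neither wild-type list also had a median of 1800 bp. The 327 islands at these regions that themselves overlap neither wild-type list were narrower (1400 bp, 1400 to 1600), so the outcome depends on which islands are taken, and open chromatin recovered in the DKO CD8 H3K27me3 library cannot be told apart from H3K27me3 by width. Reads per kb were 24 for all islands at these regions, 20 for the islands away from them and 23.2 for all DKO CD8 H3K27me3 islands. If H3K27me3 replaced H3K27ac there, DKO CD8 H3K27ac was predicted to be rarer, and it was found in 96.5% (94.2 to 98.1), against 98.0% (97.6 to 98.4) of H3K4me3 regions without DKO CD8 H3K27me3, intervals that overlap and leave replacement in some of the cells open.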
